A study of Rattus norvegicus with 31 samples.

How the data were processed

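Total RNA of rat testes was hybridised as labelled RNA to Affymetrix rat genome arrays, with 14 arrays from sham-treated rats, 11 from rats with hormone ablation and 6 from rats with ablation and estradiol. The deposited values are MAS5 signals which the authors placed on a logarithmic scale, taken here as log2. Neither the version of MAS5, the base of the logarithm nor the scaling reference is stated in the labels. The base was read as 2. The spike-in controls cre and bioB lay 5.127 apart on average in the 25 arrays that have control values. No expected distance was set against this for any base, so it does not settle the base. Fold changes printed here rest on the reading as log2. The 6 newer arrays carry 2 decimals and no control values. Detection calls were not used here. Values were used as deposited, with no further normalization and no pseudocount, since they were already logarithmic. For arrays the number of replicates sets the precision.

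The table held 31099 probe sets, of which 57 Affymetrix controls were left out. A probe set was kept where its value exceeded the 40th percentile of its own array (between -1.93 and -1.75) in at least 6 arrays, the size of the smallest group, which left 21269. Gene names came from the platform annotation, brought to current symbols by Entrez gene number where one matched (20758 probe sets). Of the 31042 probe sets other than controls, 20826 had 1 gene symbol, 436 had several and 9780 had none and are called unnamed. Each of 11387 genes was represented by its kept probe set of highest mean over all arrays.

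Samples were grouped by treatment as the labels give it. Differences were tested per probe set with limma 3.58.1 in R 4.3.3, fitting all 31 arrays with 3 groups and moderating the variances with a trend on mean signal. Tests were 2-sided, p-values were adjusted by Benjamini and Hochberg over all kept probe sets, and a probe set is called at an adjusted p under 0.05. The 3 comparisons were ablation against sham, estradiol plus ablation against ablation, and estradiol plus ablation against sham. A separate fit compared the sham arrays by their description. Replicate numbers did not pair the samples: correlations of their deviations between groups were -0.086 to 0.047 over 11 pairs and -0.18 to 0.059 over 6, while between sham and estradiol arrays they were -0.011 to 0.38, with 3 of 6 over 0.1. No batch term could be fitted, since all 6 newer arrays are the estradiol group.

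The 22 gene lists, of 450 entries, were written before the data were examined, as were the filter, the tests and all alternatives but those named as added later. Of the entries, 376 had a probe set named here, through older symbols where needed. Some genes stand in more than 1 list. Each list was tested with camera at a preset correlation between genes of 0.01 and again with a correlation estimated from the arrays, adjusted over the 22 lists within a comparison. Counts of called members are given over all probe sets tested and adjusted over the list alone. Shares of unnamed probe sets were compared with Fisher's exact test. The relation of the changes with ablation and with estradiol was compared with 100 simulated draws without change and with the ablation arrays split into 6 odd and 5 even replicates.

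Named genes followed a rule set before the data were examined. It takes, per comparison, the 10 highest and the 10 lowest log2 changes among called genes with exactly 1 symbol, leaving out provisional symbols, then up to 4 called members of each list with the smallest adjusted p, and 20 genes fixed in advance whatever their p. Genes with full values in the text are a part of these, and any other gene is said to be chosen after its values were seen. After the data were seen, the change of each named gene was also taken with every value below the 40th percentile of its array raised to that percentile, which is called the change above the filter level. It is printed for most changes where the group with the lower values averaged below that level, and shows how much of the change lies above it, without a test of its own. Gene list tests and list means used the values as deposited, also those below that level. The pipeline was tested on simulated data with 200 changed probe sets. Noise was drawn independently for each probe set, with no correlation between genes and no difference between deposits. The rates that follow hold for such data and do not give the false share among the real calls. For estradiol plus ablation against ablation the pipeline recovered 29.9% of changes of 0.5, 83.6% of changes of 1 and 100% of changes of 2 (log2), with a false share of 4.7%. For ablation against sham the recoveries were 40.3%, 86.6% and 100% with a false share of 5.62%, and for estradiol plus ablation against sham 40.3%, 82.1% and 100% with a false share of 3.27%.

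Alternatives were no filter, a filter at the 60th percentile, quantile normalization, centring each array on its median, only the compared groups in the fit, robust moderation, no trend, array weights, replicate number as a block, 1 probe set per gene, each array left out in turn, and only the sham arrays of either description. For the gene lists the mean of all kept probe sets per gene was also tried. After the data were seen, a further alternative left out 10 arrays, those with a score over 0.2 in size on the first component of the deviations from group means (14.6% of the variance within groups), which left 7 sham, 9 ablation and 5 estradiol arrays. These are called the arrays at the ends of the first component. Quantile normalization for the unnamed probe sets was also added then.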

Results

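The data were gene expression values from 31 Affymetrix rat genome arrays of total RNA from rat testes. The rats were LBNF1 males, 25 to 27 weeks old, whose lower abdomen had received 6 Gy of radiation. In 14 arrays the rats had sham treatment. In 11 arrays they had hormone ablation, meaning a gonadotropin-releasing hormone antagonist together with flutamide, an antiandrogen. In the remaining 6 arrays estradiol was given on top of the ablation. The labels call each array a biological replicate. The 25 sham and ablation arrays belong to an earlier series and the 6 estradiol arrays are newer, so the estradiol group and its deposit cannot be told apart. The label of the estradiol arrays also names supplementation with follicle-stimulating hormone while listing estradiol as the compound, and the group is read here as the series title and design give it. Array medians of the deposited values lay between -1.44 and -1.24 (log2). For arrays the number of replicates limits the precision, and no sequencing depth applies.

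Hormone ablation against sham asks what withdrawal of gonadotropins and androgen action did to the irradiated testis. By mean log2 change, the 2 lists of Leydig cells, which make testosterone, were the lowest of the 22 gene lists. The means were -1.29 for markers and -0.91 for steroid synthesis, followed by -0.72 for extracellular matrix. Insl3, a peptide hormone of Leydig cells, was 22.4-fold lower, a log2 change of -4.49 ± 0.19 (SE, 11 against 14 arrays, adjusted p = 1.79e-20), and all 11 ablation arrays lay below every sham array. Cyp17a1, the steroid 17-alpha-hydroxylase needed to make androgens, was 4.61-fold lower (log2 change -2.20 ± 0.11, same arrays), and Cyp11a1, which catalyses the first step from cholesterol to steroids, was 3.76-fold lower. Ces1d, a carboxylesterase, was 13.5-fold lower (-3.75 ± 0.15). Greb1, a gene that estrogen induces in many tissues, was 8.59-fold lower (-3.10 ± 0.21). Its ablation arrays averaged below the filter level, the 40th percentile of each array, and with every such value raised to that level the change was -2.76, given below as the change above the filter level. Inhbb, which encodes the inhibin beta B subunit made by Sertoli cells, was 2.81-fold higher (1.49 ± 0.12, adjusted p = 1.35e-12).

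With limma, 4128 of 21269 probe sets passed an adjusted p of 0.05, of which 1947 were higher and 2181 lower with ablation (47.2% higher). After quantile normalization 2652 were higher and 2355 lower (53% higher), after centring each array on its median 2291 and 2353 (49.3% higher), and with only the 4 sham arrays described as irradiated 848 and 1469 (36.6% higher). Lower calls were the majority in each of these but quantile normalization. At least a 2-fold change was seen in 436 of them, 110 higher and 326 lower. At 1 probe set per gene, 1051 genes were higher and 1460 lower of 11387. Other genes among the 10 with the lowest values were Card9 (log2 change -4.17, but -0.33 above the filter level), Mrap (-3.67, but -0.62 above the filter level), Nat8f5 (-3.17), Ass1 (-3.13), Isyna1 (-3.10), Adh1c (-3.05) and Defb24 (-3.03). Isyna1 makes inositol phosphate from glucose phosphate, and Ass1 is a urea cycle enzyme. Highest were Zfp536 (3.08), Bod1l1 (2.08), Sall4 (2.01), Aspn (1.88), Myom2 (1.87), Rcor2 (1.60), Cpeb1 (1.58), Xcl1 (1.57), Rbm44 (1.55) and Erhl1 (1.54). In all 10 the sham arrays averaged below the filter level, so the sizes and order of these changes rest on values that low. Above the filter level the changes were 1.36 for Myom2, 1.32 for Zfp536, 1.17 for Aspn, 0.70 for Rbm44, 0.55 for Bod1l1, 0.47 for Rcor2, 0.46 for Sall4, 0.20 for Erhl1, 0.20 for Cpeb1 and 0.18 for Xcl1. Sall4 encodes a transcription factor of spermatogonia and Cpeb1 a protein that controls translation in germ cells. Of the 80 called genes that the naming rule picked, 68 had all ablation arrays on the same side of the sham mean, and in 22 the group with the lower values averaged below the filter level. Using only the 4 sham arrays described as irradiated gave 2317 called probe sets, and with them Xcl1 (adjusted p = 0.0549) and Rbm44 (adjusted p = 0.08) lost their calls.

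Genes of Leydig cells and of cholesterol synthesis fell as groups. Of 14 Leydig steroid synthesis genes tested, 10 were lower and 1 higher with ablation (11 lower and 1 higher adjusted over the list alone), and the list passed camera with an adjusted p of 4.68e-11 at the preset correlation and 0.00082 with an estimated correlation. Star, which carries cholesterol into mitochondria, was 1.81-fold lower (-0.86 ± 0.14), Tspo was 2.84-fold lower (-1.51) and Hsd17b3, which makes testosterone, was 2.48-fold lower (-1.31 ± 0.23). The 1 higher gene was Hsd3b1 (0.39, adjusted p = 0.0364), named after its value was seen. Of 13 Leydig cell markers, 8 were lower and 1 higher (10 and 1 adjusted over the list alone; list adjusted p = 1.89e-11, and 0.00082 with an estimated correlation). The higher marker was Lhcgr, the receptor for luteinizing hormone, at 1.27-fold (0.35 ± 0.11, adjusted p = 0.0183), a call lost with only the 4 sham arrays described as irradiated (0.19, adjusted p = 0.364) and without the arrays at the ends of the first component (0.14, adjusted p = 0.496). Cholesterol synthesis and uptake had 13 of 19 genes lower and 0 higher (14 lower adjusted over the list alone; list adjusted p = 3.49e-08, and 0.0111 with an estimated correlation). Among them, Acat2 was 2.10-fold, Cyp51 1.86-fold and Lss 1.57-fold lower.

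Genes of the extracellular matrix and genes that respond to estrogen were lower too. Matrix genes had 19 of 26 lower and 1 higher (20 and 1 adjusted over the list alone; list adjusted p = 8.63e-16, and 0.00129 with an estimated correlation). Col1a1, a fibrillar collagen chain, was 6.18-fold lower (-2.63 ± 0.15), Col3a1 2.98-fold lower (-1.58) and Timp1, an inhibitor of matrix proteases, 4.95-fold lower (-2.31). Of 17 estrogen-responsive genes, 8 were lower and 0 higher (10 lower adjusted over the list alone; list adjusted p = 1.53e-05, and 0.0174 with an estimated correlation). Besides Greb1 these included Igf1, a growth factor, at 6.36-fold lower (-2.67 ± 0.10), the growth hormone receptor Ghr at 2.36-fold lower (-0.48 above the filter level) and Myc at 1.74-fold lower.

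Genes of Sertoli cells, spermatogonia and dividing cells were higher. Of 17 Sertoli cell markers, 7 were higher and 0 lower (9 higher adjusted over the list alone; list adjusted p = 1.17e-05, and 0.0182 with an estimated correlation). Espn was 1.56-fold higher (0.65 ± 0.14) and Inha, the inhibin alpha subunit, 1.33-fold higher (0.41 ± 0.10), which with only the 4 sham arrays described as irradiated had an adjusted p of 0.0507. Of 15 genes of undifferentiated spermatogonia, the germ line stem and progenitor cells, 6 were higher and 0 lower (7 higher adjusted over the list alone; list adjusted p = 0.00392, and 0.0182 with an estimated correlation). Besides Sall4, the receptor Ret was 2.26-fold higher (1.18 ± 0.18, but 0.26 above the filter level), Epcam 2.02-fold higher (1.01 ± 0.14, and 0.88 above the filter level) and the transcription factor Sox3 1.78-fold higher (0.83 ± 0.13). The list test took Sall4 at 2.01 and Ret at 1.18, as deposited. Part of the rise of this list thus rests on values below the filter level. Of 21 proliferation genes, 9 were higher and 0 lower (10 higher adjusted over the list alone; list adjusted p = 3.31e-06, and 0.0223 with an estimated correlation), with Mki67 at 2.11-fold (1.07 ± 0.16), Prc1 at 2.02-fold and Ccnb1 at 1.45-fold.

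Further lists passed at the preset correlation and not with an estimated one. Peritubular myoid and smooth muscle genes had 8 of 16 lower and 0 higher (8 lower adjusted over the list alone; list adjusted p = 0.000358, but adjusted p = 0.121 with an estimated correlation), with Tagln 2.11-fold lower. Macrophage genes had 11 lower and 4 higher of 19 (12 and 5 adjusted over the list alone; list adjusted p = 0.00471, but adjusted p = 0.321 with an estimated correlation). The scavenger receptor Cd163 was 2.00-fold lower and the complement gene C1qb 1.93-fold lower. The 4 higher members, named after their values were seen, were Cd74, RT1-Da, RT1-Db1 and RT1-Ba, genes of antigen presentation by class II molecules, with log2 changes of 0.59, 0.43, 0.40 and 0.29. Endothelial genes had 4 of 12 lower and 0 higher (5 lower adjusted over the list alone; list adjusted p = 0.0246, but adjusted p = 0.139 with an estimated correlation). Ribosomal protein genes had 0 of 15 called either way (0 adjusted over the list alone; list adjusted p = 0.0321, but adjusted p = 0.603 with an estimated correlation). Without the arrays at the ends of the first component the endothelial list had an adjusted p of 0.0585.

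The other 10 lists did not pass. Androgen-responsive Sertoli cell genes had 3 of 9 lower and 0 higher (3 lower and 1 higher adjusted over the list alone; list adjusted p = 0.0854), led by Tubb3 (-1.62) and Eppin (-1.52, and -1.13 above the filter level). Secreted factors acting on spermatogonia had 6 lower and 3 higher of 21 (10 and 4 adjusted over the list alone; list adjusted p = 0.0854), with a median of 0.02 against a mean of -0.38 and a test direction that was down. Of its 25 named entries, 7 also stand in other lists, among them Insl3 (-4.49) and Igf1 (-2.67), which pull its mean down. Under the mean of all kept probe sets per gene this list of secreted factors passed (adjusted p = 0.0255). Among these factors the chemokine Cxcl12 was 2.21-fold lower and Kitlg, the ligand of the Kit receptor, 1.38-fold higher (0.47 ± 0.08). Differentiating spermatogonia had 3 higher and 1 lower of 6 (3 and 1 adjusted over the list alone; list adjusted p = 0.263). The lower gene was Kit (-0.76 ± 0.26, adjusted p = 0.0387), whose call was lost without any single array of sham 1, 5, 9, 10, 11 or 13 or of ablation 1, 3, 5 or 6, with an adjusted p of up to 0.0695 (without sham 5, -0.65), and with either description of the sham arrays alone. Hormone receptors had 4 lower and 2 higher of 10 (4 and 3 adjusted over the list alone; list adjusted p = 0.399). Retinoid metabolism had 4 lower and 1 higher of 13 (4 and 1 adjusted over the list alone; list adjusted p = 0.456). Immediate early and stress genes had 1 higher of 19 (1 adjusted over the list alone; list adjusted p = 0.439), and lymphocytes and mast cells 1 lower of 9 (1 adjusted over the list alone; list adjusted p = 0.786). Epididymis and efferent ducts (5 genes, adjusted p = 0.748), red blood cells (4 genes, adjusted p = 0.936, median 0.0075 against a mean of -0.04 and a test direction that was down) and meiotic and postmeiotic germ cells (9 genes, adjusted p = 0.596) had 0 called, and 0 adjusted over the list alone. In the last of these, Prm1 and Tnp1, which pack DNA in spermatids, had log2 changes of 1.33 ± 1.05 (adjusted p = 0.418) and 1.37 ± 1.07 (adjusted p = 0.41). The sham arrays averaged below the filter level for Tnp1, whose change above it was -0.06, of opposite sign. Prm1 ranged from -6.11 to 5.78 across the sham arrays.

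Estradiol plus ablation against ablation asks which genes estradiol changed once testicular hormones were suppressed, and is the comparison that the series title is about. Greb1 was 7.86-fold higher with estradiol, a log2 change of 2.98 ± 0.26 (SE, 6 against 11 arrays, adjusted p = 1.1e-09; 2.63 above the filter level). Isyna1 was 3.93-fold higher (1.97 ± 0.12) and Dio3, which inactivates thyroid hormones, 2.91-fold higher (1.54 ± 0.21, and 1.33 above the filter level). A pair of Leydig cell genes fell further: Cyp17a1 was 3.61-fold lower (-1.85 ± 0.14, adjusted p = 2.89e-11) and Insl3 3.69-fold lower (-1.89 ± 0.23, adjusted p = 1.16e-06, and -1.52 above the filter level). Myh6, a myosin heavy chain best known from heart muscle, was 4.50-fold lower (-2.17 ± 0.17). For each of these 6 genes all 6 estradiol arrays lay beyond every ablation array.

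With limma 1173 of 21269 probe sets were called, 126 higher and 1047 lower with estradiol, or 10.7% higher. After quantile normalization 312 were higher and 988 lower, and after centring each array on its median 275 were higher and 871 lower, or 24% higher with either, so the balance of directions depended on the scaling. At least a 2-fold change was seen in 277 probe sets (20 higher and 257 lower). By gene, 83 were higher and 311 lower of 11387, 8 and 30 of them by at least 2-fold. Other genes at the top were Htr4 (log2 change 1.51), Slpi (1.28), Mgarp (1.17), Sult1c2 (1.08), Id1 (1.02), Pllp (1.00) and Myom2 (0.99). Above the filter level Htr4 was at 0.65, Slpi at 0.63, Mgarp at 0.59 and Sult1c2 at 0.63. Id1 encodes an inhibitor of differentiation, and Slpi a protease inhibitor, whose call was lost without any single array of estradiol 1, 4, 5 or 6 or of ablation 2, 5, 6 or 9 (adjusted p of up to 0.0953, without estradiol 5, 1.20). Other genes at the bottom were Aldoc (-1.83), Bod1l1 (-1.81, adjusted p = 0.0503 with the replicate block), Fbxl22 (-1.65), Atp6v1c2 (-1.63), Ces1d (-1.49) and Nars2 (-1.49). Above the filter level Aldoc was at -0.94, Bod1l1 at -0.60, Fbxl22 at -0.21, Atp6v1c2 at -0.26 and Nars2 at -0.91. Of the 39 called genes that the naming rule picked, 38 had all estradiol arrays on the same side of the ablation mean, 11 lost their call in at least 1 fit that left out an array, and in 13 the group with the lower values averaged below the filter level.

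Undifferentiated spermatogonia was the list that passed at the preset and at an estimated correlation. Of its 15 tested genes, 2 were higher and 0 lower (5 higher adjusted over the list alone; list adjusted p = 0.000242, and 0.0109 with an estimated correlation). Ret was 1.75-fold higher (0.81 ± 0.22, adjusted p = 0.0237) and Sox3 1.53-fold higher (0.61 ± 0.16, adjusted p = 0.013). The call of Sox3 was lost without estradiol 1 (0.46, adjusted p = 0.076), with the replicate block (adjusted p = 0.06) and without the arrays at the ends of the first component (0.44, adjusted p = 0.107). That of Ret was lost without estradiol 1 (0.70, adjusted p = 0.089), estradiol 5 (adjusted p = 0.0563), estradiol 6 (adjusted p = 0.0621) or the arrays at the ends of the first component (0.61, adjusted p = 0.0814).

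Among 17 estrogen-responsive genes, 3 were higher and 0 lower (4 higher and 1 lower adjusted over the list alone; list adjusted p = 0.00032, but adjusted p = 0.0785 with an estimated correlation). Beside Greb1 these were Myc, a growth regulator, at 1.90-fold (0.92 ± 0.15) and Igf1 at 1.42-fold (0.51 ± 0.13, adjusted p = 0.0134), a call lost without estradiol 1 (0.39, adjusted p = 0.0719). Proliferation genes had 1 higher and 0 lower of 21 (1 adjusted over the list alone; list adjusted p = 4.57e-05, but adjusted p = 0.0785 with an estimated correlation). That gene was Ccna2 (0.79 ± 0.24, adjusted p = 0.0424). Its call was lost without any single array of ablation 2, 4, 6, 7, 9 or 10 or of estradiol 1 to 6, with an adjusted p of up to 0.105 (without estradiol 1, 0.73). Immediate early and stress genes had 1 higher of 19 (1 adjusted over the list alone; list adjusted p = 0.000242, but adjusted p = 0.201 with an estimated correlation), namely Dusp1 (0.96 ± 0.26), whose call was lost without estradiol 5 (0.88, adjusted p = 0.0697) or estradiol 6 (0.75, adjusted p = 0.109) and without the arrays at the ends of the first component (0.85, adjusted p = 0.0789).

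No Leydig cell or cholesterol list passed with an estimated correlation. Of 14 steroid synthesis genes, 2 were lower and 0 higher (2 and 2 adjusted over the list alone; list adjusted p = 0.775, with a median of 0.10, a mean of -0.03 and a test direction that was up). The other lower gene was Cyp11a1 at 1.48-fold (-0.56 ± 0.13), while Star (0.11 ± 0.18, adjusted p = 0.817) and Hsd17b3 (0.14 ± 0.29, adjusted p = 0.862) were not called, and Hsd17b3 was at -0.13 without ablation 4. Of 13 Leydig cell markers, 3 were lower and 0 higher (3 lower adjusted over the list alone; list adjusted p = 0.0372, but adjusted p = 0.25 with an estimated correlation and 0.0688 without the arrays at the ends of the first component). The 3 were Insl3, Ces1d and Hsd11b2 (-0.36 ± 0.11, adjusted p = 0.0366). The call of Hsd11b2 was lost without any single array of ablation 5, 6, 9 or 10 or of estradiol 2 to 6, with an adjusted p of up to 0.102 (without estradiol 2, -0.31), after quantile normalization (adjusted p = 0.0837), after median centring (adjusted p = 0.0872), with the replicate block (adjusted p = 0.0649), with only the compared groups in the fit (adjusted p = 0.0608), with 1 probe set per gene (adjusted p = 0.0553) and without the arrays at the ends of the first component (adjusted p = 0.054). Lhcgr was not called (0.11 ± 0.13, adjusted p = 0.754). Cholesterol synthesis and uptake had 2 lower of 19 (4 lower adjusted over the list alone; list adjusted p = 0.00115, but adjusted p = 0.201 with an estimated correlation). They were Cyp51 (-0.44 ± 0.12), whose call was lost without estradiol 5 (-0.40, adjusted p = 0.0638), estradiol 6 (-0.38, adjusted p = 0.0827) or with the replicate block (adjusted p = 0.132), and Insig1 (-0.41 ± 0.11), whose call was lost without estradiol 3 (-0.35, adjusted p = 0.0891), estradiol 5 (-0.33, adjusted p = 0.123), after median centring (adjusted p = 0.0747) or with the replicate block (adjusted p = 0.206).

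The other lists did not pass in this comparison. Extracellular matrix had 3 higher and 1 lower of 26 (3 and 4 adjusted over the list alone; list adjusted p = 0.568, with a median of -0.03, a mean of 0.02 and a test direction that was up). Lum (0.67 ± 0.15), Col6a3 (0.52 ± 0.11) and Col6a1 (0.49 ± 0.11) were higher and Col3a1 (-0.40 ± 0.10) lower. Sertoli cell markers had 1 higher of 17 (2 adjusted over the list alone; list adjusted p = 0.918), namely the transcription factor Dmrt1 (0.65 ± 0.14), which germ cells also express. Inhbb was not called (0.13 ± 0.15, adjusted p = 0.716). Inha stood at 0.39 ± 0.13 (adjusted p = 0.0577), and was called after quantile normalization (adjusted p = 0.0242), after median centring, with array weights, with only the compared groups in the fit, and without any single array of sham 4, 7 or 11, ablation 2 or 5, or estradiol 3 (0.47, adjusted p = 0.0276). Retinoid metabolism had 1 higher of 13 (1 adjusted over the list alone; list adjusted p = 0.104), the retinoic acid binding protein gene Crabp2 at 1.65-fold (0.72 ± 0.14). Androgen-responsive Sertoli cell genes had 1 lower of 9 (1 adjusted over the list alone; list adjusted p = 0.0866, and 0.0468 after quantile normalization), Serpina5 at -0.64 ± 0.12. Secreted factors acting on spermatogonia had 1 higher and 1 lower of 21 (1 and 1 adjusted over the list alone; list adjusted p = 0.775, median 0.02 against a mean of -0.05 and a test direction that was up), and Kitlg was not called (-0.11 ± 0.10, adjusted p = 0.668).

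Meiotic and postmeiotic genes had 1 lower of 9 (1 adjusted over the list alone; list adjusted p = 0.427). The lower gene was Prm1 (-4.59 ± 1.33, adjusted p = 0.0309, and -2.06 above the filter level), while Tnp1 was at -3.15 ± 1.35 (adjusted p = 0.206, and -0.58 above the filter level). The call of Prm1 was lost without any single array of ablation 4, 5 or 9 or of estradiol 1, 2, 3, 4 or 6, with an adjusted p of up to 0.0812 (without estradiol 6, -4.37), with the replicate block (adjusted p = 0.105) and with robust moderation (adjusted p = 0.0505). Prm1 lay between -6.09 and -2.43 in the estradiol arrays and between -5.14 and 4.18 in the ablation arrays. Myoid and smooth muscle genes had 1 lower of 16 (1 adjusted over the list alone; list adjusted p = 0.266), and epididymis and efferent ducts 1 lower of 5 (1 adjusted over the list alone; list adjusted p = 0.839, median -0.04 against a mean of 0.02 and a test direction that was down). Hormone receptors had 0 called of 10 (1 higher and 1 lower adjusted over the list alone; list adjusted p = 0.427). Differentiating spermatogonia (adjusted p = 0.104, Kit at 0.27 ± 0.33), macrophages (adjusted p = 0.245), lymphocytes and mast cells (adjusted p = 0.442), endothelium (adjusted p = 0.354), red blood cells (adjusted p = 0.775) and ribosomal proteins (adjusted p = 0.447, and 0.0118 after quantile normalization) had 0 called, and 0 adjusted over the list alone.

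**Figure D1:**
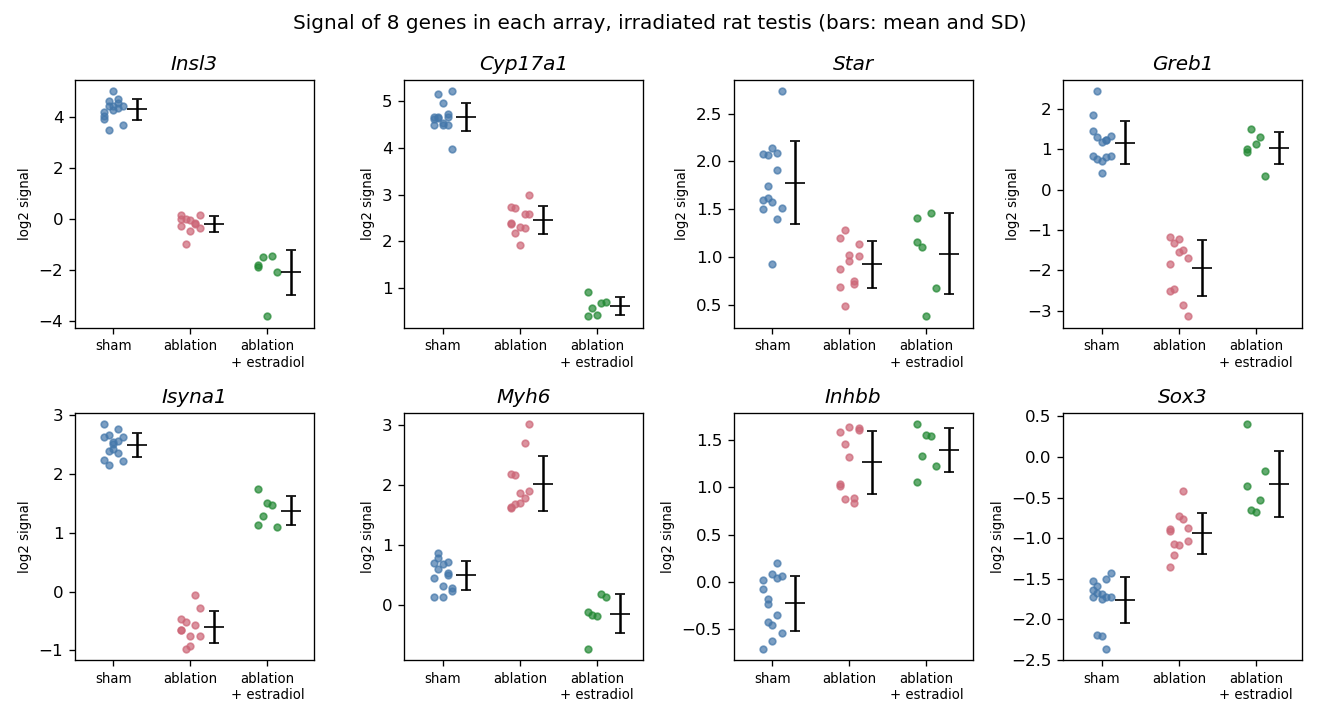
Deposited log2 signal (vertical axes) of 8 genes in each of 31 arrays, by group (horizontal axes); points are arrays and bars are the group mean and SD. Greb1 averaged 1.17 in sham, -1.93 with ablation and 1.05 with estradiol, while Insl3 averaged 4.28, -0.21 and -2.09. The averages of -1.93 and -2.09 lie below the filter level.

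Probe sets without a gene name here made up much of what was lower with estradiol than with ablation, but not of what was lower with estradiol than in sham. They were 25.5% of the 21269 probe sets tested, 54.9% of the 1047 called lower (575 probe sets; Fisher's exact test, 2-sided, odds ratio 3.87, 95% interval 3.40 to 4.40, p = 3.05e-96) and 74.7% of the 257 that were lower by at least 2-fold. Among the 126 called higher they were 15.9% (odds ratio 0.55, p = 0.0134). That last difference was not called among probe sets above the median signal (odds ratio 0.70, p = 0.367), and at a 2-fold change the odds ratio was 1.25 (p = 0.613). Against sham they were 25.4% of the 2211 called lower with estradiol (odds ratio 0.994, 95% interval 0.896 to 1.10, p = 0.918), 24.5% of the 432 lower by at least 2-fold (p = 0.696) and 17.3% of the 882 called higher (odds ratio 0.602). With ablation against sham they were 31.3% of the 1947 called higher (odds ratio 1.37, 95% interval 1.24 to 1.52, p = 1.56e-09), 39.1% of the 110 higher by at least 2-fold and 12.6% of the 2181 called lower (odds ratio 0.391). The 575 averaged -0.76 in sham, -0.44 with ablation and -1.36 with estradiol. Of them, 225 were called higher with ablation than in sham and 301 were called lower with estradiol than in sham. The larger part of their average drop thus lay below the sham level. They were picked as low in these same estradiol arrays, which inflates that part. What these probe sets measure was not analysed here.

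Probe sets called in both comparisons mostly moved in opposite directions. Of them, 403 were higher with ablation and lower with estradiol, against 95.8 expected if the calls were independent, and 54 were lower with ablation and higher with estradiol, against 12.9 expected. Lower in both were 68 (107 expected) and higher in both 10 (11.5 expected). Unnamed probe sets were 225 of the 403 and 4 of the 54. Between estradiol plus ablation and sham, 314 of the 403 and 32 of the 54 were not called, which does not show that levels were equal. The largest group, that of 403, held 110 genes, among them Myh6, Bod1l1 and Nars2. What kinds of genes it held was not tested. Greb1, Isyna1, Sult1c2, Htr4, Myc and Crabp2 were among the 41 genes of the smaller group of 54. Insl3, Cyp17a1, Ces1d and Cyp11a1 were among the 41 genes that were lower in both.

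The ablation arrays enter both changes with opposite signs, which alone gives a negative relation and raises the counts of opposite calls above those expected from independence. Across the 21269 probe sets, which are not independent replicates, the changes had a Pearson r of -0.32 and a Spearman rho of -0.37. Simulated groups without change gave a mean r of -0.45 over 100 draws. They held no ablation change, which in the data widens the spread that r is divided by. The simulated r is therefore no measure of what the shared arrays give in the data. The covariance was -0.04 against -0.0156 in the simulated groups. With different ablation arrays for each change (6 odd and 5 even replicates), r was -0.20 and -0.17 with covariances of -0.0271 and -0.0233. The relation thus stayed negative without shared arrays, though smaller in size. Its size was not tested, and the deposit of the estradiol arrays cannot be told apart from estradiol here.

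Estradiol plus ablation against sham gives the state of the testis under the combined treatment. Insl3 was at least 64.4-fold lower, a log2 change of -6.01 above the filter level (-6.37 ± 0.22 as deposited, SE, 6 against 14 arrays, adjusted p = 2.06e-22), as its estradiol arrays averaged below that level. Ces1d was 37.9-fold lower (-5.24 ± 0.18) and Cyp17a1 16.7-fold lower (-4.06 ± 0.14), and all 3 genes were lower in all 6 arrays. Spermatogonial and dividing cell genes were higher, with Sox3 at 2.71-fold (1.44 ± 0.15) and Mki67 at 2.40-fold (1.26 ± 0.19). Sall4 (2.65 ± 0.54 as deposited) and Ret (1.99 ± 0.22) lay below the filter level in all 14 sham arrays and were at 0.75 and 0.97 above it. The list of undifferentiated spermatogonia below was tested on the values as deposited. Myom2, a sarcomere protein gene, was higher by 2.87 ± 0.18, and by 2.36 above the filter level. Greb1 stood at -0.13 (adjusted p = 0.815), which does not show that its levels were equal.

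With limma 3093 probe sets were called, 882 higher and 2211 lower (28.5% higher), and 544 changed at least 2-fold (112 higher and 432 lower). After quantile normalization 1753 were higher and 1963 lower (47.2% higher), and after median centring 1483 and 1890 (44% higher), so here too the balance of directions depended on the scaling. By gene, 601 were higher and 1355 lower. The other lowest genes were Hp (-4.11), Aldoc (-4.04), Card9 (-3.96), Ass1 (-3.91), Mrap (-3.88), Tekt3 (-3.61) and Nat8f5 (-3.31). Above the filter level Hp was at -2.97, Aldoc at -3.15, Card9 at -0.37, Mrap at -0.66 and Tekt3 at -2.08. The other highest were Rcor2 (2.75), Aspn (2.23), Erhl1 (2.21), Stc1 (2.19), Slc25a31 (2.06), Cpeb1 (1.97) and Zfp536 (1.96). Above the filter level Rcor2 was at 1.29, Aspn at 1.52, Erhl1 at 0.60, Slc25a31 at 0.79, Cpeb1 at 0.33 and Zfp536 at 0.54. In 25 of the 80 called genes that the naming rule picked, the group with the lower values averaged below the filter level. Hp encodes haptoglobin, which binds hemoglobin, and Stc1 a secreted glycoprotein. With only the 4 sham arrays described as irradiated 1693 probe sets were called and Slc25a31 lost its call (adjusted p = 0.0517), as it did with the replicate block (adjusted p = 0.0772), while Zfp536 lost it without the arrays at the ends of the first component (1.42, adjusted p = 0.0812).

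Of the 22 lists, 8 passed with the preset and with an estimated correlation. Leydig steroid synthesis had 7 lower and 2 higher of 14 (9 and 2 adjusted over the list alone; list adjusted p = 1.82e-07, and 0.00312 with an estimated correlation), with Cyp11a1 5.55-fold lower and Star 1.68-fold lower (-0.75 ± 0.17, adjusted p = 0.0735 with the replicate block). Hsd17b3 was 2.25-fold lower (-1.17 ± 0.28), a call lost with only the 4 sham arrays described as irradiated (adjusted p = 0.0556) and without the arrays at the ends of the first component (adjusted p = 0.0581). Leydig cell markers had 8 lower and 1 higher of 13 (10 and 1 adjusted over the list alone; list adjusted p = 3.74e-12, and 0.000607 with an estimated correlation). The higher marker was again Lhcgr (0.46 ± 0.13, adjusted p = 0.0125), a call lost without estradiol 2 (0.38, adjusted p = 0.0596), with only the 4 sham arrays described as irradiated (0.30, adjusted p = 0.205) and without the arrays at the ends of the first component (0.26, adjusted p = 0.246). Cholesterol synthesis and uptake had 15 lower and 0 higher of 19 (16 lower adjusted over the list alone; list adjusted p = 9.49e-12, and 0.0016 with an estimated correlation), and extracellular matrix 16 lower and 1 higher of 26 (20 and 2 adjusted over the list alone; list adjusted p = 3.74e-12, and 0.00312 with an estimated correlation), with Col1a1 5.41-fold lower.

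Sertoli cell markers had 7 higher and 0 lower of 17 (7 higher and 1 lower adjusted over the list alone; list adjusted p = 0.000152, and 0.0418 with an estimated correlation), with Inhbb 3.08-fold higher (1.62 ± 0.14) and Inha 1.75-fold higher (0.81 ± 0.12). Androgen-responsive Sertoli cell genes had 3 lower and 0 higher of 9 (3 lower adjusted over the list alone; list adjusted p = 0.00422, and 0.0373 with an estimated correlation), with Tubb3 3.94-fold lower and Eppin 2.64-fold lower (-1.14 above the filter level). Undifferentiated spermatogonia had 8 higher and 0 lower of 15 (11 higher adjusted over the list alone; list adjusted p = 4.1e-07, and 0.000555 with an estimated correlation). Proliferation genes had 12 higher and 0 lower of 21 (18 higher adjusted over the list alone; list adjusted p = 3.74e-12, and 0.0016 with an estimated correlation), among them Ccna2 at 3.02-fold (1.59 as deposited, 0.88 above the filter level).

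Lists whose call was lost with an estimated correlation were differentiating spermatogonia with 3 higher of 6 (4 adjusted over the list alone; list adjusted p = 0.0231, but adjusted p = 0.0695 with an estimated correlation), myoid and smooth muscle with 8 lower of 16 (8 adjusted over the list alone; list adjusted p = 6.1e-05, but adjusted p = 0.0695 with an estimated correlation), immediate early and stress genes with 5 higher of 19 (9 adjusted over the list alone; list adjusted p = 0.000749, but adjusted p = 0.211 with an estimated correlation) and ribosomal proteins with 0 of 15 (0 adjusted over the list alone; list adjusted p = 0.0101, but adjusted p = 0.531 with an estimated correlation). The spermatogonial list also had an adjusted p of 0.0718 after quantile normalization and 0.113 without the arrays at the ends of the first component.

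The remaining 10 lists did not pass against sham. Estrogen-responsive genes had 7 lower and 1 higher of 17 (7 and 2 adjusted over the list alone; list adjusted p = 0.0592), though the list passed after quantile normalization (adjusted p = 0.0448) and without the arrays at the ends of the first component (adjusted p = 0.0124). Macrophages had 6 lower and 3 higher of 19 (9 and 4 adjusted over the list alone; list adjusted p = 0.0949), and secreted factors acting on spermatogonia 6 lower and 3 higher of 21 (6 and 3 adjusted over the list alone; list adjusted p = 0.216). Among the latter, Kitlg was 1.28-fold higher (0.36 ± 0.10, adjusted p = 0.00998), a call lost without estradiol 2 (0.29, adjusted p = 0.0531), with only the 4 sham arrays described as irradiated (0.29, adjusted p = 0.222) and without the arrays at the ends of the first component (0.27, adjusted p = 0.128). Endothelium had 2 lower of 12 (2 adjusted over the list alone; list adjusted p = 0.216), hormone receptors 3 lower and 1 higher of 10 (3 and 2 adjusted over the list alone; list adjusted p = 0.787, median 0.01 against a mean of -0.16 and a test direction that was down) and retinoid metabolism 2 lower and 1 higher of 13 (2 and 1 adjusted over the list alone; list adjusted p = 0.787). Epididymis and efferent ducts had 1 higher and 1 lower of 5 (1 and 1 adjusted over the list alone; list adjusted p = 0.887, median -0.02 against a mean of 0.11 and a test direction that was up). Lymphocytes and mast cells had 1 lower of 9 (0 adjusted over the list alone; list adjusted p = 0.787), and red blood cells (adjusted p = 0.787) and meiotic and postmeiotic germ cells (adjusted p = 0.887) had 0 called, and 0 adjusted over the list alone. In the last list Prm1 stood at -3.26 ± 1.27 (adjusted p = 0.085, and 0.0486 without sham 4) and Tnp1 at -1.78 ± 1.30 (adjusted p = 0.426), and Kit of the differentiating spermatogonia at -0.49 ± 0.32 (adjusted p = 0.365). All estradiol arrays lay below the filter level for Prm1 (highest -2.43) and Tnp1 (highest -4.92), so the sizes of these changes rest on values that low.

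**Figure D2:**
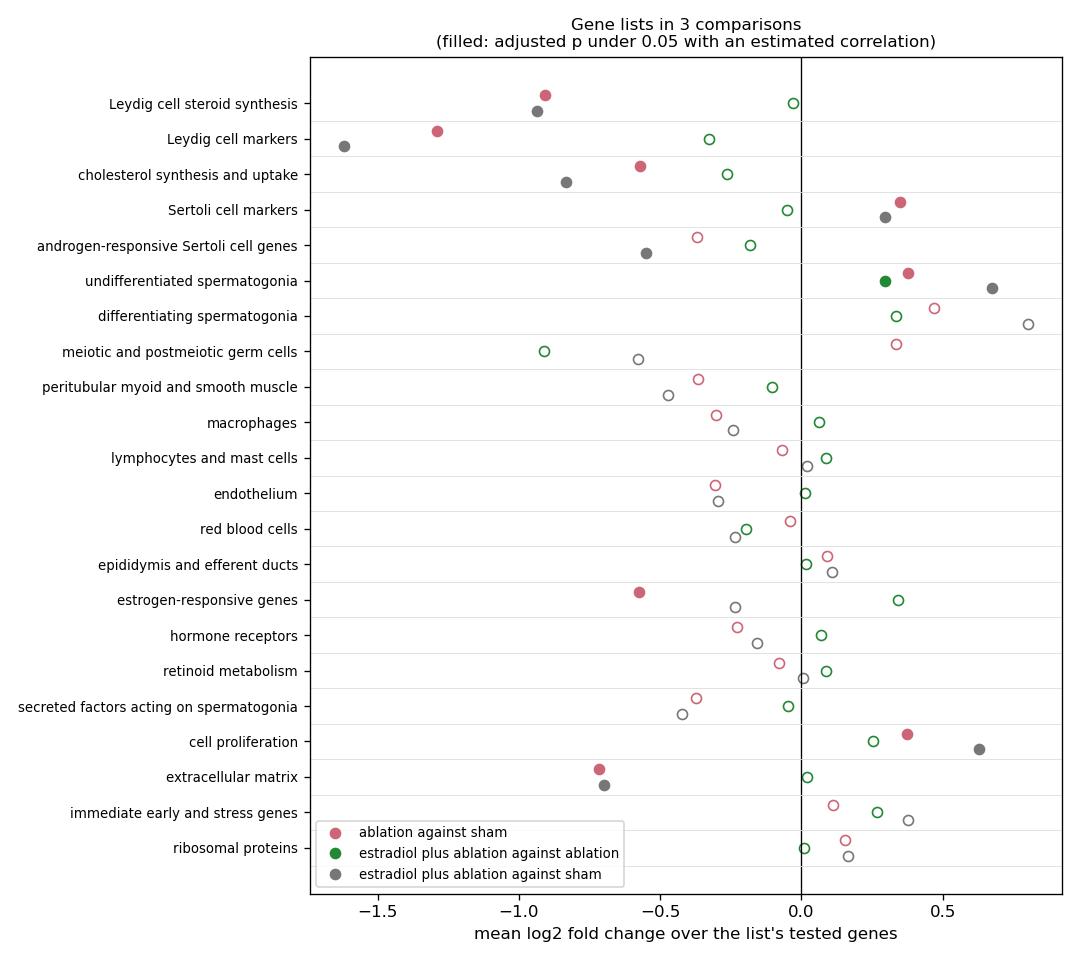
Mean log2 fold change (horizontal axis) of the tested genes of each of 22 gene lists (vertical axis) in the 3 comparisons; filled points have an adjusted camera p under 0.05 with an estimated correlation. Undifferentiated spermatogonia averaged 0.38 with ablation, 0.30 with estradiol against ablation and 0.68 with estradiol against sham. These means use values as deposited, which for Sall4 and Ret lay below the filter level in all 14 sham arrays.

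Of the 14 sham arrays, 10 are described in the labels as control and 4 as irradiated, although other fields say that all were irradiated. With limma 0 of 21269 probe sets were called between these descriptions (smallest adjusted p of 1), and 513 had an unadjusted p under 0.05 where 1063 would be expected by chance. Several genes chosen before the data were examined could not be reported: Rhox5, Amh, Esr1, Esr2, Gdnf and Pgr lay below the filter, with group means from -7.04 to -2.26, and Fshr and Stra8 had no probe set named here.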

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

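The tests of the deposit difference, of the scaling, of protamine noise, of haploid germ cell RNA and of RNA length were chosen after the result was seen; the test of low signal and the splits of the arrays were planned. In the 6 estradiol arrays, 7 of 104 named genes had an array whose gap to its nearest neighbour took an unusual share of the range, where chance gives about 1 in 20, or 5.2. Estradiol 3 stood apart for Crabp2 (0.662 of the range) and for Insl3 (0.73), where it lay at -3.82 and the others between -2.09 and -1.45. Estradiol 5 stood apart for Prm1 (0.639, at -2.43), Plvap (0.667) and Zfp536 (0.655). Estradiol 6 stood apart for Egr1 (0.653) and Slc25a31 (0.764). No biological explanation was tested for these single arrays.

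Probe sets called lower with estradiol than with ablation were rich in probe sets without a gene name here (54.9% against 25.5% of all), while those called lower with estradiol than in sham were not (25.4%). Their low signal does not account for this, as the odds ratio stratified over 10 bands of mean signal was 4.41 (95% interval 3.86 to 5.04), and neither does the scaling, with an odds ratio of 3.90 after quantile normalization. A deposit difference unrelated to ablation is argued against as the only cause: probe sets picked with the odd ablation arrays were higher in the 5 even ablation arrays than in sham by a median of 0.289 (matched unnamed sets 0.0169 to 0.0738), and those picked with the even arrays by 0.385 in the 6 odd arrays (matched 0.0388 to 0.113). The matched ranges resample probe sets, which are not independent. Exact permutation of the arrays gave p = 0.0249 for the 5 even and p = 0.000929 for the 6 odd arrays, on the mean change. The 575 probe sets averaged -0.76 in sham, -0.44 with ablation and -1.36 with estradiol, with 225 called higher with ablation and 301 called lower with estradiol than in sham. The larger part of the average drop thus lay below sham. Picking them as low in these same estradiol arrays inflates that part, and no other estradiol arrays exist here. All estradiol arrays are newer. A deposit difference behind that part, or one acting on transcripts that ablation raised, cannot be told apart from estradiol. An effect of estradiol on these transcripts, the biological reading the design offers, therefore stays a hypothesis.

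Protamine and transition protein transcripts differed widely between arrays of one group, with Prm1 from -6.11 to 5.78 in sham. Noise of a single probe set is argued against, since Prm1 and Tnp1 followed each other across the 14 sham arrays (r = 0.929, permutation p = 2e-05, adjusted 0.00012, and rho = 0.776, p = 0.00185, adjusted 0.00386; r = 0.761 without the 2 arrays farthest from the median) and the 11 ablation arrays (r = 0.814, permutation p = 0.00261, and rho = 0.845, p = 0.00193). RNA of haploid germ cells in some testes or arrays may be the source, as Prm1 followed the mean of 20 other meiotic and postmeiotic genes, 7 of them above the filter, in sham (r = 0.849, permutation p = 0.00023, adjusted 0.00046, and rho = 0.556, p = 0.0423, adjusted 0.0612). Without the 2 farthest sham arrays that r was 0.511, and in the ablation arrays it was 0.874 (permutation p = 0.00016, rho = 0.927, p = 2e-04). Whether such RNA arose in the testis or by carry-over between samples was not tested.

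Arrays of one group spread along 1 component that held 14.6% of the variance within groups. Length of the labelled RNA, read from the difference between actin 3' and 5' probe sets, could be involved, as the component followed it in sham (r = 0.734, permutation p = 0.00203, adjusted 0.00304, and rho = 0.538, p = 0.051, adjusted 0.0612; r = 0.536 without the 2 farthest). Across the 11 ablation arrays r was 0.191 (permutation p = 0.568, and rho = 0.273, p = 0.419; -0.119 without the 2 farthest). The estradiol arrays have no actin control values here, so the explanation stays open, and no biological explanation was tested. All permutation tests were 2-sided, and the relations across arrays were 6 in all.

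Other splits of the same arrays into groups of the same sizes were counted, 100 for each comparison with the real split included. For the called probe sets, 1 of 100 splits gave as many for ablation against sham (real 4128, highest other 805), for estradiol plus ablation against ablation (1173, highest other 2) and for estradiol plus ablation against sham (3093, highest other 203). In each that 1 was the real split, so chance is argued against as far as 100 splits can tell. For the gene lists at the preset correlation, 6 of 100 splits gave as many as the real 12 for ablation against sham (highest other 13). For estradiol plus ablation 3 of 100 did against ablation (real 6, highest other 9) and 3 of 100 against sham (real 12, highest other 12). Other splits thus reached the real count in each comparison, so chance is not excluded for the counts of lists. For the sham arrays by description the real count was 0, which any split matches, so the 100 of 100 splits that gave as many (highest other 78) decide nothing.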

How the results depend on the processing

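The alternatives that leave out the arrays at the ends of the first component, and quantile normalization for the unnamed probe sets, were chosen after the data were seen; all others were planned. Pseudocounts of other sizes could not be applied, as the values were already logarithmic. Counts of called probe sets stayed within 1.5 times the reported ones under most alternatives. With 1 probe set per gene, which tests fewer probe sets, 2661 (ablation against sham), 269 (at least 2-fold), 308 (estradiol plus ablation against ablation), 37 (at least 2-fold) and 324 (estradiol plus ablation against sham, at least 2-fold) were called. A filter at the 60th percentile, which also tests fewer, gave 160 and 342 at 2-fold for the estradiol comparisons. Using only the 4 sham arrays described as irradiated, which are fewer, gave 2317 and 1693 against sham. With replicate number as a block the counts were 3185, 878 and 2349. Leaving out each array in turn gave 3723 to 4456, 831 to 1242 and 2539 to 3195. Without the arrays at the ends of the first component they were 2835, 1148 and 2396. The lists passing for estradiol plus ablation against ablation went from 6 to 1 with an estimated correlation, which allows for genes that vary together. The relation of the changes was -0.1989 and -0.1663 with the ablation arrays split, which removes the shared arrays. For unnamed probe sets called higher the odds ratio was 0.7017 above the median signal and 1.253 at 2-fold, on fewer probe sets; the cause was not tested. Hsd17b3 in estradiol plus ablation against ablation ranged from -0.127 (without ablation 4) to 0.2309 on leaving out an array and was called in none of these fits. For named genes, 77 of 80, 28 of 39 and 68 of 80 calls held in every fit that left out an array. Without the filter, which tests more probe sets, 3898, 1137 and 2938 were called. Of these, 597, 345 and 691 changed at least 2-fold, against 436, 277 and 544 with the filter.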

Other observations

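The tests of Leydig cell number and of further probe sets were chosen after the result was seen, and the genes of the next paragraph were chosen after their values were seen, as was Dio3 for the step from sham to ablation.

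Id3 was 1.68-fold higher with estradiol than with ablation (log2 change 0.75 ± 0.20, SE, adjusted p = 0.0171), while Id2 (0.08 ± 0.25, adjusted p = 0.916) and Id4 (0.48 ± 0.16, adjusted p = 0.0674) were not called. The thyroid hormone enzyme gene Dio3 had not been called with ablation against sham (0.36 ± 0.16, adjusted p = 0.116), where both groups averaged below the filter level. Omd, osteomodulin, was lower with ablation and higher with estradiol (-0.74 ± 0.08, then 0.72 ± 0.11), as was Smoc1 (-0.53 ± 0.09, then 0.84 ± 0.11), while Dpt, dermatopontin, was lower in both steps (-1.10, then -1.14). Ephx1, a microsomal epoxide hydrolase, was 3.00-fold lower with ablation and 1.92-fold higher with estradiol. Fads1, a fatty acid desaturase, was lower in both steps (-1.60 ± 0.11, then -1.002 ± 0.14). Per3 was 2.33-fold lower with estradiol (-1.22 ± 0.22, adjusted p = 0.00028), whereas 7 other clock genes looked up were not called: Per1 (-0.65 ± 0.21, adjusted p = 0.0611), Nr1d1 (0.08 ± 0.13, adjusted p = 0.819), Hlf (-0.14 ± 0.10, adjusted p = 0.525), Tef (-0.06 ± 0.13, adjusted p = 0.861), Bmal1 (0.19 ± 0.15, adjusted p = 0.584), Dbp (-0.01 ± 0.17, adjusted p = 0.991) and Per2 (-0.38 ± 0.14, adjusted p = 0.14).

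Fewer Leydig cells could account for lower Insl3 and Cyp17a1 with estradiol. The test took 18 Leydig list genes that fell with ablation: their median change with estradiol was -0.0755 (95% bootstrap interval -0.46 to 0.15). It was -1.89 for Insl3 (-1.52 above the filter level) and -1.85 for Cyp17a1. Of the 18, 5 were lower and 0 higher, and Hsd11b2 lost its call in 9 of the 31 fits that left out an array. The genes were picked as low in the same ablation arrays, which pushes their changes with estradiol upward. The interval resamples genes rather than rats. A fall of these genes in proportion to Insl3 was not seen, but the bound for this test was set after the list medians were seen and the lower end of the interval came close to it. For these reasons the test does not decide on the number of Leydig cells. A change of transcription in Leydig cells, or a loss of cells, stays open.

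Unnamed probe sets might behave as further probe sets of named genes do. Of unnamed probe sets 10.6% were called lower with estradiol, against 3.77% of further probe sets of named genes and 2.73% of the chosen ones (odds ratio of unnamed against further 3.03, 95% interval 2.52 to 3.65), which argues against that reading.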
